A study of Homo sapiens with 6 samples.

How the data were processed

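Peripheral blood mononuclear cells from donors with autoimmune nodopathy and neurofascin 155 (NF155) antibodies (AIN) and from control donors were profiled with droplet-based 5-prime single-cell RNA sequencing. The libraries compared here each pooled cells of several donors. Per the labels' protocols, dead cells were removed, B cells were enriched in some samples, which the labels do not list, and donors carried hashtag antibodies. The matrices used here are 1 AIN pool, 3 control pools and 1 mixed pool of an AIN and a control donor, and the title of each names 2 donors. A second AIN library was not analysed here beyond its barcode list.

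The deposited matrices hold whole-number UMI counts per gene and barcode, without normalization. Per the file headers, the mixed pool was counted with Cell Ranger 4 and the AIN pool and control pool 1 with Cell Ranger 7.1.0. The headers of control pools 2 and 3 name no version, and the genome build is not given in the sources used here. The mixed pool's matrix lists 727993 barcodes without cell calling, and the others hold called cells. Per the submitters' processing notes the authors used Seurat, with no version given. No deposited cell annotation was used here. All 5 pools list the same 36601 genes, and 99.0755% or more of each pool's barcodes belong to the barcode list of the mixed pool. Judged by this barcode list alone, restricting the controls to the same chemistry removed no pool. A shared barcode list does not establish the same chemistry version.

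Barcodes with at least 500 UMIs, at least 250 genes and under 10% mitochondrial UMIs were kept. This left 7226 barcodes in the AIN pool, 6871, 9046 and 9621 in control pools 1, 2 and 3, and 8392 in the mixed pool. Their summed UMIs were 62384273 in the AIN pool, 65385548, 27087556 and 61756455 in the control pools, and 37764930 in the mixed pool. Hashtags were called with HTODemux (Seurat 5.3.0) in the mixed pool and control pools 2 and 3. The AIN pool and control pool 1 hold no hashtag counts, so their donors could not be separated and the pool was the unit of every test. Hashtags of control pool 3 were weak, with median counts of 7 and 1 per cell. Which hashtag marks which donor of the mixed pool is not given in the sources used here, so its cells entered no comparison between groups.

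Doublets were removed with the hashtags and with Scrublet (scanpy 1.11.5). Its automatic threshold marked at most 0.0119% of a pool, so the top 6% of scores were removed instead, which with ties came to 6.05% to 7.03%. Cells with transcripts of 2 lineages (at least 3 UMIs, and at least 25% of the usual level, of B, T or monocyte markers) were also removed. They made up 13.2% of the AIN pool and 18.6%, 15.9% and 8.86% of control pools 1, 2 and 3. In the mixed pool 0% of cells and 0% of its 557 hashtag doublets were marked. The filter used only lineages with enough reference cells in a pool, and the mixed pool kept 23 CD4 T cells and 3 CD14 monocytes. Its 0% therefore need not mean that such cells were absent. These filters left 5986, 5402, 6256, 8280 and 7547 cells in the AIN pool, control pools 1, 2 and 3 and the mixed pool.

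Cells were integrated across pools with Seurat's reciprocal PCA (2000 variable genes, 30 components, 20 neighbours) and clustered at resolution 1, and B cells again at 0.8. Immunoglobulin, T cell receptor, HLA, ribosomal, mitochondrial, sex-linked and haemoglobin genes were kept out of the clustering. Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 markers detected in 25% of cells. Integration, the score threshold, the removal of 2-lineage cells and the rules that left clusters unnamed were set after seeing the data and before any test between groups. Clusters with median UMIs under 40% of their pool's median stayed unnamed and held 12.5% of AIN pool cells and 14%, 4.28% and 3.74% of cells in control pools 1, 2 and 3. Clusters with transcripts of 2 lineages in at least 25% of cells held 15.5% of the AIN pool and 7.09%, 16.7% and 14.3% of control pools 1, 2 and 3. Among clustered B cells, 5.49% of the AIN pool and 3.88%, 25.7% and 4.7% of the control pools lay in a cluster led by genes of other cell types and stayed unnamed.

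UMI counts were summed per pool and class. The AIN pool was compared with the 3 control pools with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.05). With a single AIN pool, the spread comes from the control pools, and the AIN pool is assumed to vary like them. Where a control pool is tested alone, the AIN pool is among the others, so the spread there includes the AIN difference. Such counts may therefore be too low and do not measure how alike the control pools are. Fold changes are log2 AIN over control with their standard error. Levels are CPM, counts scaled by TMM library sizes, as a mean ± SD over the 3 control pools and a single value for the AIN pool. Immunoglobulin and T cell receptor segments, sex-linked genes and 3 HLA-DRB genes were left out of the tests, 652 features in all. Genes are named by the symbols that the feature files pair with Ensembl identifiers. Tested on simulated data, edgeR recovered 82% of genes changed 4-fold in B cells, 74% in naive B cells, 66% in memory B cells, 56% in CD4 T cells and 48% in CD14 monocytes. Of genes changed 2-fold it recovered 16%, 12%, 8%, 12% and 10% in that order, so changes of that size are mostly missed.

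Gene lists were fixed before the data were examined and tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the fixed lists of a class, and again with an estimated correlation. Lists of hypoxia-inducible factor (HIF) targets and of glucocorticoid-responsive genes were added after the gene tables had been seen, and their p-values are adjusted over all lists of a class, fixed and added, except where given over the 2 added lists alone. Differences between classes in the AIN to control effect were tested with an interaction term in edgeR over the same pools, and simulated 8-fold differences were recovered for 85.5% of genes for B cells against monocytes and 94.5% against CD4 T cells. Against single control pools, a list's median log2 ratio (5 CPM added) was set among 10000 random lists matched on expression, and also on gene length, as a description, and only the ratio of HIF targets against the control pool of the same software version served as a test.

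Genes were named by a rule fixed before the data were examined. It took, per class, the 8 largest rises and the 8 largest falls past the test, with at least 10 CPM in the higher group and the AIN pool outside the range of the controls, and up to 2 genes per list with the smallest p. Of the genes it named, 11 in B cells, 8 in naive and 9 in memory B cells are among the 10 leading genes of a B cell cluster and are not given as results, an exception made after their values were seen. Further genes are named as members of their lists, chosen after their values were seen, and in the B cell classes without those that lead a B cell cluster. Shares of cells have exact Clopper-Pearson 95% intervals, and intervals and limits from a count of 0 (3 counts) cover counting error only. Shares were compared by an exact two-sided permutation test over pools, which with 1 pool against 3 has 4 splits and cannot give a p under 0.25. Light chains needed 5 UMIs and 80% of a single kind, isotypes 3 UMIs of constant genes, and heavy chain variable genes 2 UMIs and 60% for the leading gene.

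Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), keeping Scrublet doublets, thinning to the smallest pool, a higher clustering resolution for the shares, other immunoglobulin minimums, and leaving out each control pool. Keeping 2-lineage cells, the higher resolution for gene tests and adding a cluster found only in the AIN pool to the monocytes were chosen after seeing the data. Fits on donor sums were not run, since the AIN pool holds no hashtag counts.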

Results

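The data compare blood cells of donors with NF155 AIN with those of control donors. In this autoimmune disease antibodies bind a protein at the paranodes, next to the nodes of peripheral nerve fibres. The AIN pool held 1935 B cells, and control pools 1, 2 and 3 held 2234, 142 and 829. Their summed B cell UMIs were 11614718 in the AIN pool and 14473398, 249095 and 3758741 in the control pools, so control pool 2 limits what B cells can show. Naive B cells numbered 482 in the AIN pool and 602, 34 and 175 in the controls, and memory B cells 1288 against 1269, 55 and 564. CD4 T cells numbered 276 in the AIN pool and 195, 518 and 1811 in the controls, and CD14 monocytes 376 against 552, 2019 and 1292. Each AIN value comes from a single pool of 2 donors, so the disease and any other feature of that library cannot be told apart, and p-values measure only the spread between control pools.

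The study concerns B cell tolerance and receptor signalling, and the first comparison asked how gene expression in AIN B cells differs from that in control B cells. B cells of the AIN pool had higher levels of the early response factor NR4A1, the plasma cell regulator IRF4, the lymph node homing receptor CCR7 and the apoptosis inducer BCL2L11, which encodes BIM. NR4A1 stood at 112 CPM against 28.3 ± 14.4 in the controls (log2 fold change 1.77 ± 0.33, edgeR adjusted p = 0.013). CCR7 stood at 213 against 65.3 ± 16.2 CPM, IRF4 at 71.9 against 17.9 ± 9.67 and BCL2L11 at 49.3 against 15.6 ± 4.15. BNIP3, a mitophagy receptor induced by low oxygen, stood at 92.1 against 10.7 ± 1.12 CPM. Among 13318 genes tested in B cells, 144 rose and 32 fell, and 1644 had an unadjusted p under 0.05. The AIN pool lay outside the range of the control pools for 172 of the 176 genes that passed. Of 29 genes named by rule that passed, 12 passed with DESeq2 and 8 with 2-lineage cells kept.

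The largest rises in B cells included LRRC32, a docking receptor for latent TGF-beta, at 17.8 against 0.0442 ± 0.0766 CPM. FOSL2, a subunit of the AP-1 transcription factor, stood at 38.5 against 2.11 ± 1.62 CPM (log2 fold change 4.93 ± 0.42). The cytoskeletal gene SPTBN4, the receptor gene GPR146 and the long non-coding RNA MIR210HG, host of a hypoxia-induced microRNA, rose by log2 fold changes of 5.20, 3.60 and 4.97. SLAMF7, a surface receptor of plasma cells, rose from 4.33 ± 3.55 to 26.9 CPM, and ICAM1, an adhesion molecule induced by NF-kB, from 2.98 ± 3.98 to 28.2 CPM. The largest falls included the long non-coding RNA IFNG-AS1, at 23.5 against 110 ± 64.9 CPM, and CNTNAP2, a cell adhesion gene of the neurexin family, at 7.15 against 29.9 ± 8.94 CPM. AC253572.2, ZC2HC1A and CCDC151 fell by 3.04, 2.91 and 3.01 on the log2 scale.

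Of the fixed lists, immediate early and activation genes rose in B cells as a set, with a median log2 fold change of 0.78 and a camera adjusted p of 0.00177 (adjusted p = 0.632 with an estimated correlation). Of its 28 tested members 2 rose, NR4A1 among them, and 7 rose when adjusted over the list alone, among them NR4A3, CD83 and EGR1. Interferon-stimulated genes rose as a set with a median of 0.43 (adjusted p 0.0139). No member of that list passed alone, and IFI44L stood at 34.4 against 10.1 ± 8.39 CPM. The receptors of tolerance and survival rose with a median of 0.23 (adjusted p 0.0497), with BCL2L11 past the test, and 6 of 23 members rose when adjusted over the list alone, among them the BAFF receptor TNFRSF13C. Heat shock and handling stress genes rose with a median of 0.51 (adjusted p 0.0402). With an estimated correlation these 3 lists had an adjusted p = 0.626. Without control pool 1 the interferon and heat shock calls ended, with adjusted p of 0.097 and 0.15, and the tolerance and survival call ended without any of the control pools, with 0.0915, 0.0918 and 0.0862.

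MHC class II machinery, which loads peptide for T cells, fell as a set in B cells with a median of -0.47 (adjusted p 0.00968), and regulators that restrain the B cell receptor fell with a median of -0.42 (adjusted p 0.0298). Transitional B genes fell with a median of -0.50 (adjusted p 0.0402). Monocyte transcripts, which come from other cells, fell with a median of -1.95 (adjusted p 0.00362), and platelet transcripts with -2.63 (adjusted p 0.0497). These 5 lists had an adjusted p = 0.626 with an estimated correlation. The MHC class II call held whichever control pool was left out. Without control pools 1 and 2 in turn, adjusted p was 0.0533 and 0.487 for the inhibitory regulators, 0.117 and 0.197 for transitional genes, and 0.0741 and 0.197 for platelet transcripts. T cell transcripts did not pass as a list, while TRBC1, a T cell receptor constant gene, rose from 2.62 ± 4.29 to 41.3 CPM and TRAC stood at 10.6 against 23.8 ± 3.82. The control SD of TRBC1 exceeds its mean, so its level varied widely between control pools. Whether counting software set the rise of TRBC1 was not tested. B cell receptor signalling had a median of -0.12 and NF-kB targets 0.46, with adjusted p of 0.211 and 0.0542, and neither passed. The naive (-0.04), memory (-0.58), atypical (-0.46) and plasma cell (-0.05) lists, NK cell transcripts (-0.79), oxidative phosphorylation (-0.22) and ribosomal proteins (0.09) did not pass, and the plasma cell list's mean was 0.23. SLAMF7 and IRF4 are the plasma cell genes that rose.

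HIF target genes, a list chosen after the data were seen, rose in B cells with a median log2 fold change of 1.60. Of 32 tested members 18 rose and none fell, and 26 rose when adjusted over the list alone. Over all 21 lists of the class its adjusted p was 1.0e-23 at the preset correlation and 0.415 with an estimated correlation, and over the 2 added lists alone the latter was 0.0395. The glycolytic genes LDHA, TPI1 and HK2 stood at 421, 722 and 24.8 CPM against 94.5 ± 30.6, 193 ± 12.8 and 3.48 ± 1.28 in the controls. P4HA1, a collagen prolyl hydroxylase, and PDK1, a kinase that inhibits pyruvate dehydrogenase, stood at 116 and 54 CPM against 26.3 ± 4.96 and 14 ± 5.24. Against control pools 1, 2 and 3 singly, the median log2 ratio of the list in B cells was 1.25, 1.58 and 1.33. Glucocorticoid-responsive genes, the other list added after the data were seen, had medians of 0.72, 0.49, 0.70, 0.72 and 0.02 in B, naive B, memory B and CD4 T cells and monocytes, with adjusted p over all lists of 0.0152, 0.0637, 0.0256, 1.9e-05 and 0.437 in that order. With an estimated correlation these were 0.577, 0.666, 0.589, 0.243 and 0.675, and over the 2 added lists alone the CD4 T cell value was 0.0382. The list's mean log2 fold changes were 0.67, 0.60, 0.64, 0.86 and 0.34 in the same order of classes. ZBTB16, a member of the list, is a leading gene of the B cell cluster that held 66.2% of naive B cells in the AIN pool.

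**Figure D1:**
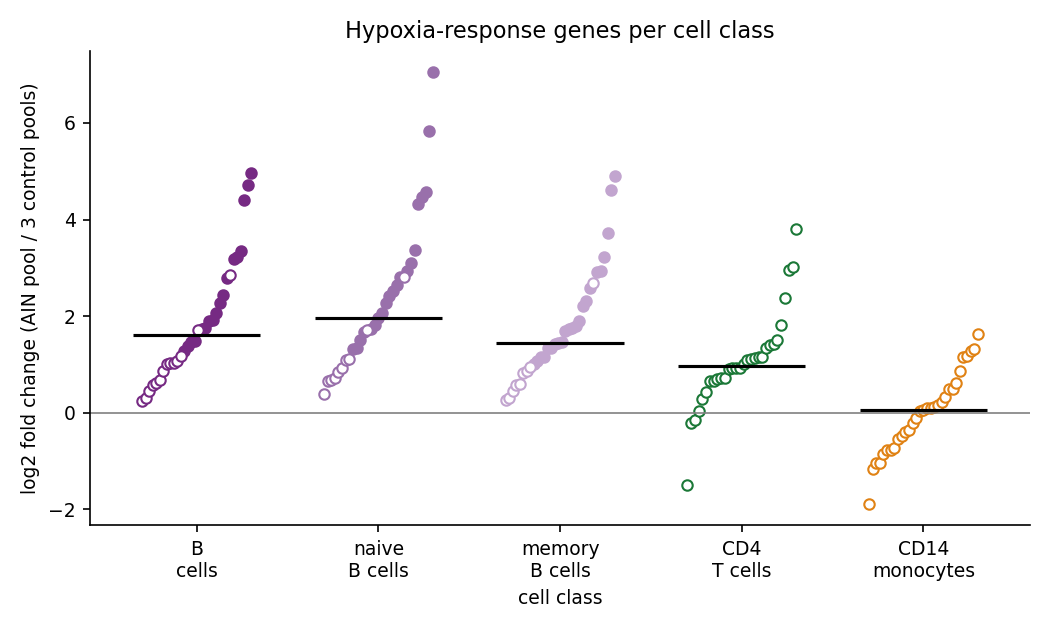
Each point is the log2 fold change (AIN pool over 3 control pools) of a HIF target gene in a cell class, filled where the edgeR adjusted p was under 0.05, and black bars are medians. The medians were 1.60, 1.96 and 1.45 in B, naive B and memory B cells, 0.96 in CD4 T cells and 0.07 in CD14 monocytes.

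The B cell count rests on control pool 1: without it 1 gene passed, which was not among the 176, and without control pools 2 and 3 the counts were 99 and 128. Control pool 3, tested as the lone pool against the other 3, gave 102 genes, while no other control pool gave any in B cells.

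Naive B cells were compared because early tolerance acts before antigen experience. They had lower levels of the inhibitory Fc receptor-like genes FCRL3 and FCRL2 and of the class II transactivator CIITA, and higher levels of the early response genes EGR1, NR4A3 and NR4A1. FCRL2 stood at 17 CPM in the AIN pool against 63.8 ± 13.6 in the controls (log2 fold change -1.97 ± 0.42, edgeR adjusted p = 0.00027), and FCRL3 at 24.6 against 86.7 ± 44.6. EGR1 stood at 82.2 against 17.4 ± 15.1 CPM and NR4A3 at 52.3 against 2.57 ± 4.45. In naive B cells 360 genes rose and 196 fell among 10007 tested, and 1839 had an unadjusted p under 0.05. The AIN pool lay outside the range of the control pools for 505 of the 556 genes that passed. Of the genes named by rule that passed, 2 of the 20 with a DESeq2 adjusted p passed there, and 39 of 39 with 2-lineage cells kept. Different clusters held most naive B cells: 66.2% of those in the AIN pool lay in the cluster with ZBTB16, YBX3 and SESN1, and 92.2%, 97.1% and 98.9% of those in control pools 1, 2 and 3 lay in the cluster with IL4R and TCL1A.

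Regulators that restrain the B cell receptor fell as a set in naive B cells, with a median log2 fold change of -0.68 (camera adjusted p 0.0046), and the receptor's own signalling genes fell with a median of -0.38 (adjusted p 0.00808). Both had an adjusted p = 0.704 with an estimated correlation. Of 22 inhibitory regulators, FCRL3, FCRL2 and the collagen receptor LAIR1 fell and the ubiquitin ligase CBLB rose. Adjusted over the list alone 8 fell, among them the Fc receptor FCGR2B at 45.1 against 79 ± 42.3 CPM and the phosphatase PTPN6 at 114 against 242 ± 72.5. None of the 32 signalling genes passed alone. BTK, the kinase downstream of the receptor, stood at 52.3 against 99.2 ± 17.5 CPM, BLNK, its adaptor, at 94.8 against 204 ± 47.6 and the receptor subunit CD79B at 391 against 763 ± 71.2.

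MHC class II machinery fell in naive B cells with a median of -0.52 (adjusted p 0.0046), with the peptide-loading modulator HLA-DOB at 68.4 against 196 ± 75.9 CPM and CIITA at 59.9 against 137 ± 9.36. Immediate early and activation genes rose with a median of 0.50 (adjusted p 0.0191), with 8 members higher and the costimulatory ligand CD86 lower at 6.26 against 31.5 ± 16 CPM. NF-kB targets and heat shock genes rose with medians of 0.68 and 0.75 (adjusted p 0.0485 and 0.025), and transitional B genes fell with -0.999 (adjusted p 0.0217). In the transitional list NEIL1, a DNA glycosylase, was among the members that rose, while PPP1R14A, PLD4 and CD24 fell. These 5 lists had an adjusted p = 0.704 with an estimated correlation. The other fixed lists did not pass in naive B cells, with medians of 0.08 for interferon-stimulated genes, whose mean was 0.05 and whose test pointed down, 0.12 for tolerance and survival, and -0.26 for plasma cell genes, whose mean was 0.15. The naive and memory lists had medians of 0.07 and 0.08 and means of -0.06 and -0.48, and T cell transcripts had a median of -0.93 with a test pointing up. Without control pool 1 the heat shock call ended, with an adjusted p of 0.21.

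The migration receptors CCR7 and GPR183 rose in naive B cells, to 387 and 133 CPM from 109 ± 14.1 and 52.4 ± 23.4, while PCDH9, a protocadherin of naive B cells, fell to 27.7 from 100 ± 9.88. LRRC32 was at least 84.4-fold higher, SPTBN4 at least 19.7-fold and ADM, a hypoxia-induced peptide hormone, at least 13.9-fold higher against a limit of 3 counts over all control pools. NEAT1, a nuclear long non-coding RNA, stood at 196 against 40 ± 7.37 CPM, and PER1, a clock gene on the glucocorticoid list, at 155 against 49.9 ± 18.2. HIF targets had a median of 1.96, with 21 of 31 members higher, none lower and 27 higher when adjusted over the list alone (adjusted p over all lists 1.9e-20, and adjusted p = 0.666 with an estimated correlation). The falls of APOO, PTPRCAP, SNRPD3 and AC004448.2 rest on control pool 3, where APOO stood at 1221 CPM against 10.2 and 31.8 in the other controls and 7.6 in the AIN pool.

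**Figure D2:**
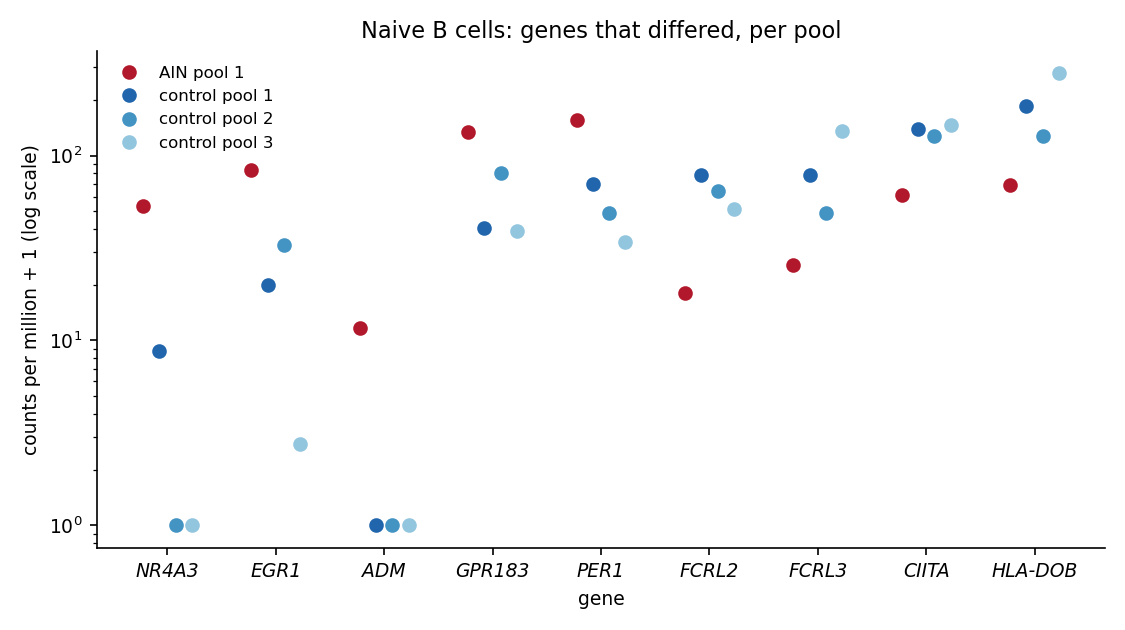
Levels of 9 genes in naive B cells (CPM plus 1, log axis), 1 point per pool. ADM is at 0 counts in all 3 control pools, and FCRL2, FCRL3, CIITA and HLA-DOB lie below all control pools in the AIN pool.

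Leaving out control pools 1, 2 and 3 in turn gave 263, 1219 and 295 genes in naive B cells, and the immediate early and NF-kB calls ended without control pool 3, with adjusted p of 0.11 and 0.243. The transitional call ended without control pools 1 and 2 (adjusted p 0.311 and 0.304), and control pools 1, 2 and 3, each tested alone against the other pools, gave 14, 0 and 47 genes.

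Memory B cells were compared to see whether the differences extend beyond the naive compartment. They had lower levels of memory-type genes, among them the transcription factor TOX and the calcium-binding gene S100A4, and higher levels of NR4A1, NR4A3, CCR7 and BCL2L11. TOX stood at 14.6 against 33.4 ± 22.2 CPM (log2 fold change -1.38 ± 0.35, edgeR adjusted p = 0.0041) and S100A4 at 158 against 448 ± 236. NR4A1 stood at 102 against 22.3 ± 11.8 CPM. In memory B cells 258 genes rose and 152 fell among 12484 tested, and 1464 had an unadjusted p under 0.05. The AIN pool lay outside the range of the control pools for 341 of the 410 genes that passed. Of 37 genes named by rule that passed, 4 passed with DESeq2 and 6 with 2-lineage cells kept, and TOX passed with neither. Cluster makeup differed here too: the cluster led by TNFSF9, CD70 and ID1 held 30.4% of AIN memory B cells and 2.84%, 18.2% and 1.42% of those in control pools 1, 2 and 3. The cluster led by COCH, AIM2 and BTNL9 held 8.23% against 26.8%, 32.7% and 50%.

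The memory B list fell with a median of -0.72 (camera adjusted p 0.00176), with 4 members lower and 8 lower when adjusted over the list alone, among them ANXA2 and ITGB1. Immediate early and activation genes rose with a median of 0.92 (adjusted p 0.00176), with 6 members higher. MHC class II machinery fell with a median of -0.46 (adjusted p 0.0408), and monocyte transcripts with -2.07 (adjusted p 0.00176). All 4 had an adjusted p = 0.604 with an estimated correlation. The interferon-induced gene IFI44L rose to 39 from 9.53 ± 10.6 CPM, while its list did not pass (median 0.44, adjusted p 0.059). NFATC1, a calcium-responsive factor of the receptor pathway, and CBLB, which restrains it, both rose, with log2 fold changes of 1.06 and 1.04. FOXO3 and TNFRSF13C of the survival list rose to 42.7 and 341 CPM from 11.8 ± 10.7 and 147 ± 42.4.

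NRARP, a feedback target of Notch, rose in memory B cells to 15.1 from 0.748 ± 0.962 CPM, and TRBC1 rose to 41.5 from 2.48 ± 4.3 while TRAC fell to 12.5 from 35 ± 15.4. The control SD of TRBC1 exceeds its mean here too, and counting software was not tested as a source. CLNK, an adaptor of immune receptors, fell to 2.43 CPM, with 7.76, 123 and 11.9 in the control pools. The fall of AC138123.1 by 6.12 on the log2 scale rests on control pool 3, with 5.07 and 17.6 CPM in the other controls and 2.04 in the AIN pool. HIF targets had a median of 1.45, with 23 of 32 members higher and none lower, and 26 higher when adjusted over the list alone (adjusted p over all lists 3.7e-24, and adjusted p = 0.589 with an estimated correlation). B cell receptor signalling (-0.06, mean 0.01) and its inhibitors (-0.13) did not pass in memory B cells.

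Leaving out control pools 1, 2 and 3 in turn gave 193, 265 and 86 genes in memory B cells, and the MHC class II call ended without control pools 1 and 3, with adjusted p of 0.246 and 0.0765. Control pools 1, 2 and 3, each tested alone against the other pools, gave 30, 0 and 140 genes.

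**Figure D3:**
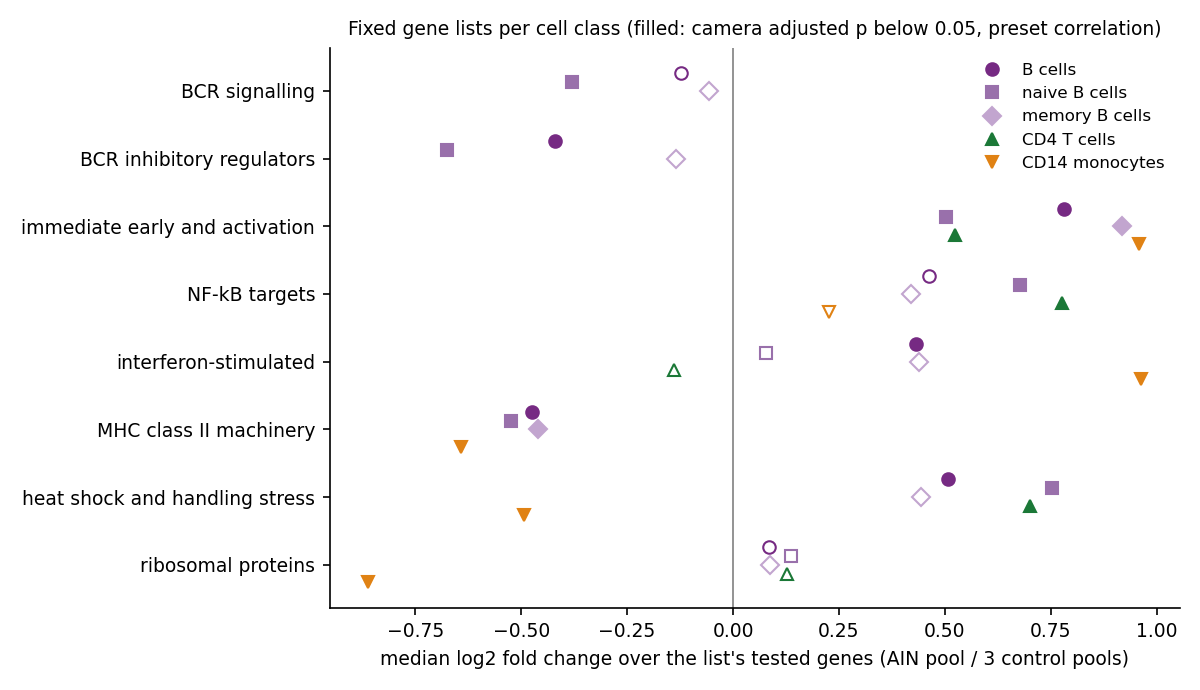
Median log2 fold change (AIN pool over 3 control pools) of fixed gene lists in each cell class, with filled symbols where camera with the preset correlation gave an adjusted p under 0.05. MHC class II medians lie below 0 in the B cell classes and CD14 monocytes, and immediate early medians lie above 0 in all 5 classes.

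CD4 T cells give help to B cells, and their comparison asked whether T cells of the AIN pool differ as well. The stress-response factor DDIT3, the cytokine signalling inhibitor SOCS1, the autophagy gene GABARAPL1, the kinase SGK1 and the phosphatase DUSP8 were higher in the AIN pool. DDIT3 stood at 126 CPM against 23.1 ± 3.22 (log2 fold change 2.40 ± 0.25, edgeR adjusted p = 0.049), GABARAPL1 at 119 against 22.3 ± 2, SOCS1 at 139 against 24.7 ± 7.98 and DUSP8 at 68.3 against 5.22 ± 1.24. In CD4 T cells 11 genes rose and none fell among 10104 tested, and 1514 had an unadjusted p under 0.05. GNG7, CHPT1 and TRAF4 also passed, with log2 fold changes of 3.91, 2.68 and 3.21. Of the genes named by rule that passed, 6 of the 6 with a DESeq2 adjusted p passed there, and 0 of 8 with 2-lineage cells kept.

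B cell transcripts were part of the CD4 T cell class: CD79A had a UMI in 23.6% (18.7% to 29%) of these cells in the AIN pool and in 16.9%, 3.09% and 3.31% in control pools 1, 2 and 3. In the 153 AIN CD4 T cells without any of 7 B cell transcripts, GNG7 and CHPT1 stood at 7.27 and 15.8 CPM of all UMIs, near the control means of 13.8 and 21.9. TRAF4 and SNX9 stood at 18.2 and 113 CPM in those cells, against 49.9 and 229 in the whole class and control means of 5 and 49.9. SGK1, SOCS1, DDIT3 and GABARAPL1 stood at 92.1, 134, 97 and 112 CPM in those cells. CXCR5, the follicle homing receptor shared by B and helper T cells, stood at 38.5 against 4.73 ± 2.27 CPM and did not pass.

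Immediate early genes rose as a set in CD4 T cells with a median of 0.52 (camera adjusted p 4.9e-05), NF-kB targets with 0.78 and heat shock genes with 0.70 (both adjusted p 0.000509), and oxidative phosphorylation fell with -0.28 (adjusted p 0.0478). With an estimated correlation these had an adjusted p = 0.681, 0.681, 0.616 and 0.794. No member passed over all genes, and 6, 4, 4 and 0 members, in that order, passed when adjusted over the list alone, with NR4A1 at 67.7 against 10.2 ± 3.92 CPM and HSPA1B at 57.8 against 7.9 ± 3.53. The lists of follicular help (0.53), T regulation (-0.61), cytotoxicity (-0.71), interferon-stimulated genes (-0.14), monocyte transcripts (-2.53) and ribosomal proteins (0.13) did not pass, nor did NK cell transcripts (-0.24), whose mean was 0.05. HIF targets had a median of 0.96 with no member past the test over all genes and 13 of 30 higher when adjusted over the list alone (adjusted p over all lists 6.9e-09, and with an estimated correlation adjusted p = 0.243, or 0.0382 over the 2 added lists alone).

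Control pools 1, 2 and 3, each alone against the other pools, gave 0, 0 and 26 genes in CD4 T cells, beside 11 for the AIN pool. Without control pool 2 no gene passed with edgeR, against 1514 genes at an unadjusted p under 0.05 and 74 with DESeq2 over all pools, and without control pools 1 and 3 the counts were 76 and 145; the oxidative phosphorylation call ended without control pools 2 and 3, with adjusted p of 0.229 and 0.0584.

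CD14 monocytes were compared as an innate class of the same pools. They had higher levels of the early response factors NR4A3, EGR3, EGR2 and NR4A1 and of the interferon-induced genes MX2 and IFIT3, and lower levels of the scavenger receptor MARCO and of ALOX5AP, which activates leukotriene synthesis. NR4A3 stood at 366 CPM against 19.9 ± 4.2, EGR3 at 107 against 3.01 ± 1.64 (log2 fold change 5.19 ± 0.39, edgeR adjusted p = 0.00019) and MX2 at 281 against 73 ± 17.1. MARCO stood at 1.58 against 43.1 ± 6.35 CPM and ALOX5AP at 4.74 against 63 ± 15.3. The class leaves out 300 monocyte-type cells of a cluster seen only in the AIN pool, and with them the log2 fold changes of ALOX5AP and HSPA8 turned to 1.0631 and 0.25515, while MX2 and IFIT3 no longer passed. In CD14 monocytes 51 genes rose and 10 fell among 12404 tested, and 1899 had an unadjusted p under 0.05. Of the genes named by rule that passed, 11 of the 12 with a DESeq2 adjusted p passed there, and 6 of 20 with 2-lineage cells kept.

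PTGS2, the inducible cyclooxygenase, rose in monocytes to 123 from 18.5 ± 9.69 CPM. INHBA, an activin subunit, and LIF, a cytokine of the interleukin 6 family, stood at 19.8 and 11.9 against 0.339 ± 0.588 and 0.257 ± 0.227 CPM. ALDH1A1, which makes retinoic acid, NRG1, a growth factor, SRD5A3 and ARL6IP5 fell by 3.10, 2.14, 3.43 and 2.13 on the log2 scale. HSPA8, a constitutive heat shock protein, fell to 64 from 258 ± 52.5 CPM without those 300 cells. S100A9, an abundant monocyte protein, stood at 4503 against 12980 ± 830 CPM and passed only when adjusted over its list alone.

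Interferon-stimulated genes rose as a set in monocytes with a median of 0.96 (camera adjusted p 3.8e-08), with 2 of 30 members past the test and 15 higher and 1 lower when adjusted over the list alone. Immediate early genes rose with a median of 0.96 (adjusted p 2.1e-07), with 5 of 28 members past the test and 11 when adjusted over the list alone. Ribosomal protein genes fell with a median of -0.86 (adjusted p 3.8e-08) and platelet transcripts with -4.52 (adjusted p 0.00328). MHC class II machinery fell with -0.64 (adjusted p 0.0316) and heat shock genes with -0.49 (adjusted p 0.0312). These 6 lists had an adjusted p = 0.623 with an estimated correlation. Oxidative phosphorylation and T cell transcripts fell with -0.46 and -0.67 (adjusted p 0.0312 and 0.0398), and had an adjusted p = 0.642 with an estimated correlation. NF-kB targets (0.23), monocyte inflammation (0.13), NK cell transcripts (-1.02) and the added HIF list (0.07, mean -0.01) did not pass.

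Without control pool 1 the monocyte count was 2 genes, of which 1 was among the 61, and without control pools 2 and 3 it was 317 and 332, while control pools 1, 2 and 3 alone against the other pools gave 0, 0 and 11. The MHC class II, heat shock and T cell transcript calls ended without control pool 1, with adjusted p of 0.078, 0.0568 and 0.3, and without control pool 2 the oxidative phosphorylation and T cell transcript calls ended, with 0.22 and 0.385.

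Cell shares asked whether early or late B cell stages are more frequent in AIN. Plasma cells made up 6.39% of B and plasma cells in the AIN pool against 3.38% ± 1.15 (SD, n = 3) in the controls, and transitional B cells 3.57% of B cells against 9.29% ± 2.81. Both lay outside the range of the control pools, with an exact permutation p of 0.25 for plasma cells, the smallest that 1 pool against 3 can give, and 0.5 for transitional cells. Single control donors spread more widely than their pools. Transitional cells made up 1.41% (1 of 71) and 14.5% of B cells of hashtags 5 and 6 in control pool 2. In control pool 3 they made up 9.41% and 5.02% for hashtags 7 and 8. Naive, memory and atypical B cells made up 24.9%, 66.6% and 4.96% of AIN B cells against 24% ± 2.92, 54.5% ± 14.8 and 12.2% ± 15.1. The atypical mean is raised by hashtag 5 of control pool 2, at 57.7% (41 of 71 cells) beside 1.45% for hashtag 6. B cells made up 34.7% of all AIN cells and 3.05% to 43.9% of control cells, a range that B cell enrichment of some samples can set.

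**Figure D4:**
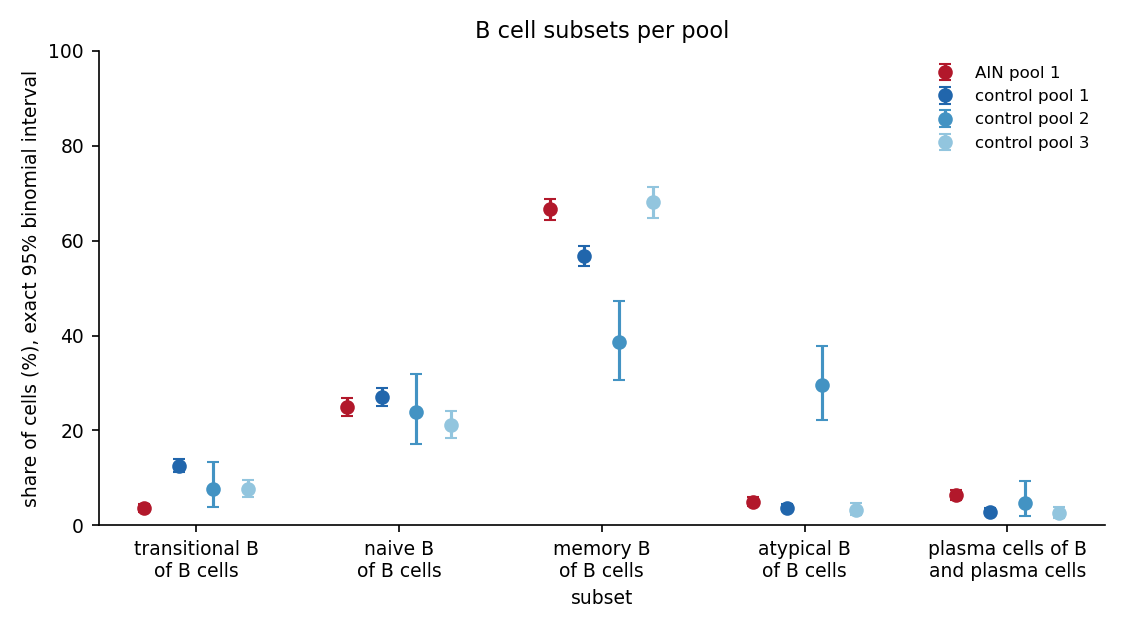
Shares of B cell subsets per pool in percent, with exact 95% binomial intervals, 1 point per pool. The AIN pool lies at 3.57% transitional B cells and 6.39% plasma cells, and control pool 2 has wide intervals from 142 B cells.

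Light chain and heavy chain use bear on early selection, since B cells that fail it can switch to a lambda light chain. Lambda was the light chain in 44.9% of naive and transitional B cells of the AIN pool (40 of 89 cells), and in 61.5%, 100% and 83.9% in control pools 1, 2 and 3 (134 of 218, 3 of 3 and 26 of 31 cells). Few cells reached the light chain minimum, and the exact permutation p was 0.25. Immunoglobulin constant genes took 0.195% of B cell UMIs in the AIN pool and 0.223%, 0.208% and 0.159% in control pools 1, 2 and 3. The cells that qualified need not stand for their class. Whether kappa and lambda transcripts were captured alike was not tested, so these shares are not estimates of the donors' light chain use. IGHV4-34, a variable gene often found in self-reactive antibodies, led in 6.63% of AIN naive B cells against 8.21% ± 1.35. The IGHV1, IGHV3, IGHV4, IGHV5 and IGHV6 families led in 18%, 46.2%, 23.9%, 5.57% and 0.796% of AIN naive B cells, against 16.3% ± 5.77, 42.1% ± 3.19, 25.3% ± 4.12, 6.91% ± 0.953 and 3.07% ± 3.18. In memory B cells, IgM or IgD, IgG and IgA led in 60.2%, 9.49% and 28.4% of AIN cells against 57.6% ± 29, 12.3% ± 10.9 and 27.9% ± 17.4. IgG4, the usual subclass of NF155 antibodies, led in 0 of 864 AIN memory B cells, which allows a share of up to 0.347%, and in 6 of 955, 0 of 16 and 2 of 278 cells in control pools 1, 2 and 3. That limit covers counting error only, and IgG calls could rest on 3 UMIs. Whether the isotypes were captured alike was not tested, so 0.347% is no ceiling on the donors' IgG4 cells. No share passed an exact permutation test, and none could with 4 splits.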

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

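All tests in this part were chosen only after the results they concern had been seen.

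HIF target genes, among them BNIP3, LDHA and P4HA1, were higher in B cells of the AIN pool than in each control pool, in data where no hypoxia was part of the design. Against the control pool counted with the same software version, 25 of 26 members were higher, with a median log2 ratio of 1.246. The version is the same in both pools, which argues against the software version as the source of that ratio. Random lists matched on expression and gene length had a median of 0.03346. The HIF list, unlike those lists, was chosen after its genes had been seen to be high against controls that include this pool. The contrast with random lists is therefore no independent evidence and decides nothing on gene length. This ratio was put in place of the list's percentile among the random lists after that had been seen. With the stricter cell filter the ratio against that pool was 1.235, against 1.246 with the usual filter, but 1879 of 1935 AIN B cells passed it, so damaged cells were not put to a test and stay open. In CD4 T cells, whose B cell transcripts stood at a median of 9.36% of the B cell level in the AIN pool and 6.407%, 1.112% and 0.715% in control pools 1, 2 and 3, the list's median log2 fold change was 0.96319. It was 0.06542 in CD14 monocytes, a class without the 300 cells of the AIN pool's own cluster (LDHA and BNIP3 at 1489 and 228.9 CPM against 79.94 and 7.186), and handling or the run of the AIN pool may account for the list and cannot be told apart from the disease in a single AIN pool.

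A cluster of 300 monocyte-type cells with high CXCL8, CXCL2, CCL2 and THBS1 was seen only in the AIN pool, held a median of 11140 UMIs per cell and entered no comparison but the alternative that adds it to the monocytes. It is called monocyte-type because CD14 monocyte was its best-scoring class. The cluster stayed unnamed, since transcripts of 2 lineages were present in at least 25% of its cells each. Of its 10 leading genes, 0 were CD14 monocyte markers. B cell markers stood at a median of 11.64% of their level in AIN B cells (5.967% to 19.95% over 7 markers), as droplets that hold several cells would give. In CD4 T cells of the same pool these 7 markers stood at a median of 9.36%. Such a level is therefore not particular to the cluster, and the test cannot tell which source brought the B cell transcripts. For the chemokines and cytokines, the median ratio to the highest other cluster of the pool over the 19 members of the fixed monocyte inflammation list was computed first and came to 0.6044, which excluded no mixture for the list as a whole. A count was adopted in its place after that median had been seen: 6 members, CCL2, CXCL2, CXCL3, THBS1, IL1RN and CXCL8, lay over 2 times above every other cluster, with CCL2 at 16.77 times and S100A8 at 0.01225 times, while IL1B and IL6 lay above every other cluster by 1.491 and 1.22 times. A mixture of the pool's other clusters may therefore explain the 11 members at lower ratios, and IL1B and IL6 stay open. It would not reach the levels of these 6 genes, but CCL2, CXCL2, CXCL3, THBS1 and CXCL8 are among the 10 leading genes of the cluster. Their excess is part of how the cluster stands out and is no independent evidence. This reading also rests on a test changed after its result, and no biological explanation was tested.

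In the mixed pool, which entered no comparison between groups, B cells of hashtag 6 and hashtag 7 differed: the median log2 ratio of hashtag 6 to hashtag 7 was 1.183 for NF-kB targets, -1.099 for regulators that restrain the B cell receptor and -1.018 for interferon-stimulated genes. The NF-kB list's ratio was 1.124 within naive and 1.029 within memory B cells. For that list alone, this argues against different proportions of naive and memory B cells as the source. The mix of clusters inside a subset was not held constant. Of naive B cells, 99.8% of hashtag 6 and 0.0725% of hashtag 7 lay in the same cluster. Each hashtag stands for a single donor, so a difference between any 2 people, or between 2 samples handled apart, may be the source and was not tested. Which hashtag carries the disease is not given in the sources used here.

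The difference between AIN and control itself differed between B cells and CD14 monocytes for 146 genes by an edgeR interaction test, 93 with a higher effect in B cells. The monocyte class leaves out the 300 cells of the AIN pool's own cluster, with which the differences from B cells were not computed. Between B cells and CD4 T cells it differed for 1 gene, with 678 at an unadjusted p under 0.05. B cells minus monocytes, the median difference of the log2 fold change was -0.23303 for immediate early genes, -0.51593 for interferon-stimulated genes, 1.0253 for heat shock genes, 0.85176 for ribosomal proteins and 1.8329 for HIF targets. B cells minus CD4 T cells, it was -0.45883 for NF-kB targets, 0.3404 for interferon-stimulated genes, -0.37992 for heat shock genes and 0.48609 for HIF targets. These lists passed camera with the preset correlation, and with an estimated correlation the smallest adjusted p among them was 0.222.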

How the results depend on the processing

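Keeping cells with transcripts of 2 lineages, the higher resolution for gene tests and adding the cluster seen only in the AIN pool were chosen after seeing the data. DESeq2 size factors, the stricter cell filter and keeping Scrublet doublets left the counts of genes within 1.5 times of 176 in B, 556 in naive B, 410 in memory B and 11 in CD4 T cells and 61 in CD14 monocytes. DESeq2 gave 36, 11, 10, 74 and 297 genes in that order. Thinning to the smallest pool gave 2, 9, 20, 70 and 176, with fewer genes tested. Without a filter on low counts 518, 515 and 558 genes passed in B cells, CD4 T cells and monocytes. With 2-lineage cells kept, 23, 18, 0 and 21 passed in B, memory B, CD4 T cells and monocytes by edgeR. The higher resolution gave 271 in memory B cells. Leaving out 1 control pool gave 1 to 128 genes in B, 263 to 1219 in naive B, 86 to 265 in memory B, 0 to 145 in CD4 T cells and 2 to 332 in monocytes. It gave 5 to 10, 6 to 7, 5 to 7, 3 to 6 and 5 to 9 fixed lists past camera, and an estimated correlation gave 0 in all 5 classes. Adding the AIN pool's own cluster to the monocytes gave 2773 genes and turned the log2 fold changes of ALOX5AP (1.0631), HSPA8 (0.25515), CD3E (4.7698), TRBC1 (4.8595), NKG7 (4.074) and ALDOA (1.3389); those cells hold T and NK cell transcripts. The share differences, AIN minus control in percentage points, turned for naive B cells at the higher resolution (-2.839) and for IgM or IgD with higher UMI minimums (-0.5493). Leaving out 1 control pool moved them from -0.5359 (without control pool 3) to 2.383 for naive B cells, -11.69 to 1.475 (without 2) for atypical B cells and -0.4775 to 0.171 (without 2) for plasmacytoid dendritic cells. They moved from -11.42 (without 3) to 17.58 for IgM or IgD, -8.981 to 1.271 (without 3) for IgG, -7.224 (without 2; -1.275 without 1) to 9.908 for IgA, -1.449 (without 2) to 4.196 for IGHV1 and -2.713 to 0.997 (without 2) for IGHV4. The cause of these moves was not tested. Of the other results under alternatives, 2494 counted as unchanged, 406 no longer passed and 142 newly passed. For genes and lists, unchanged meant the same side of the threshold, and those that passed under neither setting could change sign. For counts it meant within 1.5 times, and for shares the same sign. Fits on donor sums were not run since the AIN pool holds no hashtag counts, and the same-chemistry alternative, judged by barcode lists alone, removed no pool. Control pool 2, with 142 B cells, limits what B cells can show.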

Other observations

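The checks in this part were chosen only after the results had been seen. Immunoglobulin variable segments took 0.916% of B cell UMIs in the AIN pool and 1.51%, 1.62% and 1.33% in control pools 1, 2 and 3. In naive B cells they took 0.884% against 1.79%, 2% and 1.74%. In the mixed pool they took 0.335% of the B cell UMIs of hashtag 6 and 1.36% of those of hashtag 7.

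In the mixed pool, 1198 of 1201 naive B cells of hashtag 6 (99.8%) and 1 of 1380 of hashtag 7 (0.0725%) lay in the cluster with ZBTB16, YBX3 and SESN1, which held 66.2% of naive B cells in the AIN pool. In B cells, immediate early and activation genes stood higher in hashtag 6 than in hashtag 7 for 21 of 22 members (median log2 ratio 0.92), and MHC class II machinery for 0 of 9 (-0.64). HIF targets had a median log2 ratio of 0.20 between the hashtags, at percentile 81.4 of matched random lists, and of -1.22 for hashtag 6 against the AIN pool. The mixed pool was counted with Cell Ranger 4 and the AIN pool with Cell Ranger 7.1.0. Software, library and donors cannot be told apart in the ratio of -1.22.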
